A study of Rattus norvegicus with 24 samples.

How the data were processed

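RNA of Zucker diabetic fatty (ZDF) rats and of Zucker lean control (ZLC) rats was compared on 24 cDNA arrays with 2 dyes. The labels give 3 tissues (adipose tissue, skeletal muscle and liver), 2 ages (6 and 12 weeks) and 4 arrays in each of the 6 groups. On every array the ZDF RNA carried Cy5 and the lean RNA of the same tissue and age carried Cy3, and no array had the dyes exchanged. A dye effect of a probe therefore enters every group's log ratio, and cancels in a difference between groups only if it is the same on all arrays. The labels do not say whether the 4 arrays of a group held separate animals, pooled RNA or repeats of 1 RNA, so all error values measure the spread between arrays.

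The deposited table holds 1 log ratio per probe and array, read here as log2 although the authors do not state the base. The authors had already centred each array: array means lay between -0.0022 and 0.0017 and medians between -0.0621 and 0.039. Image analysis, background correction, spot filtering and the rule for empty cells are not given in the sources used here. The direction of the ratio is not stated either and was taken as ZDF over lean. Genes raised in fa/fa rats in textbooks had been fixed as a check of the direction, but it decided little. Pklr in liver at 6 weeks was 0.14 ± 0.04 (SD, n = 4) with an adjusted p of 0.33, and at 12 weeks it was -0.40 ± 0.25 (SD, n = 4) with an adjusted p of 0.0104, lower under the assumed direction, although the check was set for the pre-diabetic age. Scd in adipose tissue was 0.06 at 6 weeks and 0.39 at 12 weeks with adjusted p of 0.91 and 0.19. Of the 240 pairs of arrays from different groups 96.7% had a positive correlation across probes (lowest r -0.30, liver 6 weeks array 3 against liver 12 weeks array 2), and no array was turned.

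The table has 5184 probes, of which 233 had no value on any array. The platform annotation gave 1 gene symbol for 1027 probes, several for 14 and none for 4143. Of the 1027, 1026 were matched to the current rat symbol by Entrez Gene number, and Faah kept the symbol of the annotation. Probes of the same symbol were averaged (6 genes), which left 5178 features with 1021 gene symbols. Probe coordinates were not in the files, so no positions are given. Arrays carried 2850 to 4362 values each, and the number of arrays limits the precision. All 24 data columns of the table were used.

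Each array was centred on its median. A feature was tested where at least 3 of the 4 arrays of every group involved had a value. limma 3.58.1 in R 4.3.3 fitted 6 group means over the 24 arrays, with its moderated two-sided tests. The tests were each group mean against 0, the log ratio at 12 weeks minus that at 6 weeks within each tissue, and the difference between each pair of tissues averaged over both ages. P-values were adjusted by Benjamini-Hochberg within each of these 12 comparisons, and an adjusted p under 0.05 was called. Errors are given as SD over arrays for group means and as the standard error (SE) of the fit for differences. Simulated data for 8 comparisons had normal noise of each feature's moderated residual SD, which limma draws toward a common value. With changes of 1 added to 200 features, the fit recovered 91% to 100% of them. On changes of 0.5 it recovered between 50% and 61%, except in the difference between liver ages, with 4%. False calls numbered from 0 (changes of 0.5 between liver ages) to 20 (changes of 1 in adipose tissue at 12 weeks). With changes of 0.5 in adipose tissue at 6 weeks they were 12, beside 50% of the 200 recovered. The noise was independent between arrays and equally wide on all of them, and the rates hold for such arrays only. In the data the SD of the log ratios of 1 array ran from 0.293 to 0.729.

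Before the data were examined, 26 gene lists and 11 lists of cell type markers were fixed. Their shift against the other features was tested with cameraPR of limma at a preset correlation of 0.01 where at least 5 members were measured, with 1 adjustment over all lists and groups. Counts of called members are given over all features and adjusted over the list alone. Random lists of 8 named genes reached an unadjusted p under 0.05 in 2.8% to 4.5% of 400 draws per group.

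The rule for named genes was also fixed beforehand. For each group it took the 8 highest and the 8 lowest features with 1 symbol that were called and had the same sign on every measured array. It added up to 4 called members of each list described, and for each difference the 5 highest and 5 lowest called genes. Genes named outside this rule are marked as chosen after their values were seen.

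Other settings fixed beforehand were the values as deposited, scaling of the arrays to a common spread, values on all 4 arrays or on at least 2, every probe on its own, a fit on the compared groups only, array weights, the replicate number as a block (statmod 1.5.0), each tissue minus the mean of the other 2 and each array left out in turn. Scaling used the limma function for median absolute values, which its scale method applies to log ratios. An average of arrays 1 and 3 and of arrays 2 and 4 within groups, and a fit without 2 muscle arrays, were added later.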

Results

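The arrays measured 4951 probes with at least 1 value, in 3 tissues of ZDF rats relative to lean rats of the same age. The ZDF strain carries the fa mutation of the leptin receptor, becomes obese and develops diabetes. The labels call 6 weeks pre-diabetic and 12 weeks diabetic, so the groups ask how expression in each tissue differed from lean before and after onset. All values are log ratios read as ZDF over lean, so that positive values stand for a stronger signal of ZDF RNA. That direction was assumed, and if the ratio ran the other way every higher and lower below would change places. Highest and lowest refer to called features with a gene symbol that met the rule for named genes, and some probes without a symbol had larger values. With the base unstated, the highest value of a named gene, 2.47 for Crmp1 in muscle at 12 weeks, is 5.56-fold if the base is 2 and 11.9-fold if the logarithm is natural. Values per array ran from 4248 to 4315 in adipose tissue, 2850 to 3888 in muscle and 3888 to 4358 in liver at 6 weeks. At 12 weeks they ran from 3965 to 4362 in adipose tissue, 3500 to 3806 in muscle and 3540 to 3775 in liver. Lepr and Lep were not measured.

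**Figure D1:**
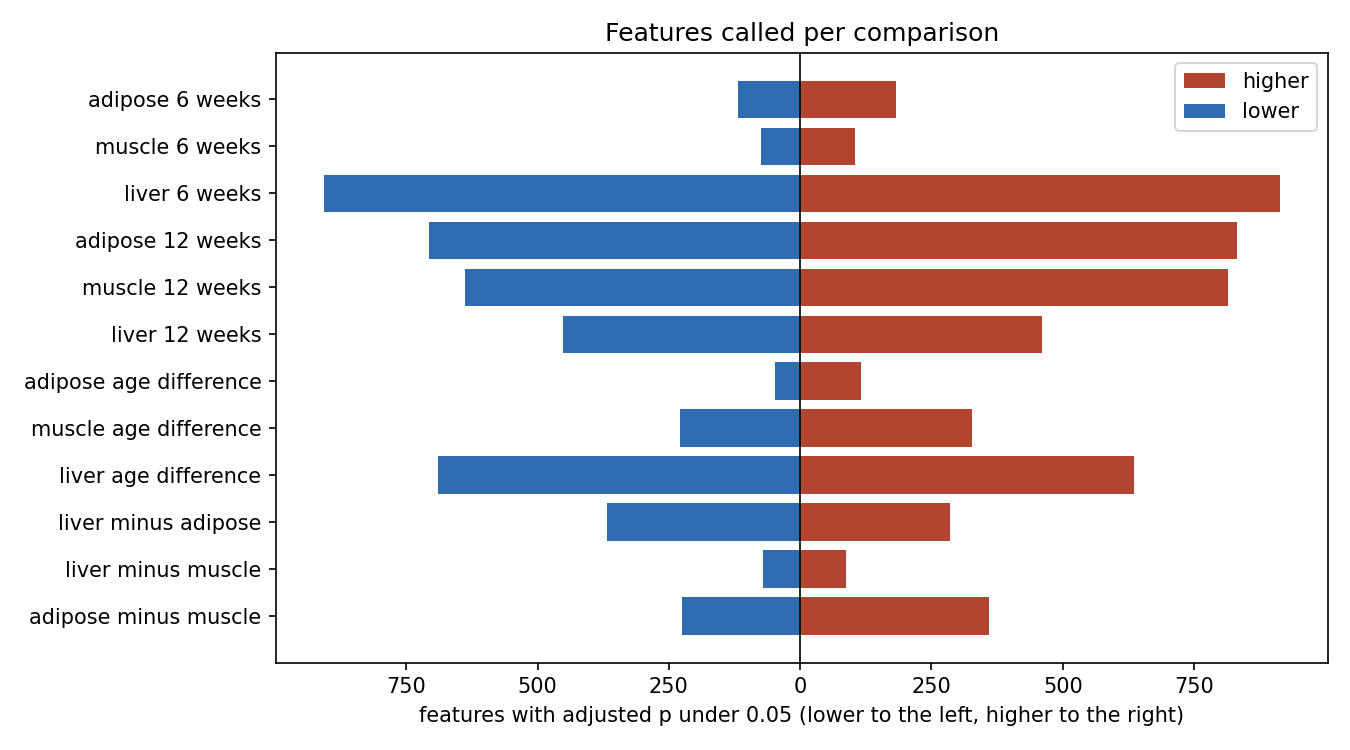
Bars give the number of features with an adjusted p under 0.05 in each of the 12 comparisons, lower to the left and higher to the right of 0. Among single groups, liver at 6 weeks had the most (1820 features) and muscle at 6 weeks the fewest (179 features).

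In adipose tissue at 6 weeks, the lowest genes encode a transporter and a hormone precursor. Slc22a3, an organic cation transporter, was -1.89 ± 0.73 (SD, n = 3) and Agt, the angiotensin precursor, was -1.41 ± 0.60 (SD, n = 3). Avp, the vasopressin precursor, fell by 0.75 ± 0.24 (SD, n = 4). The highest were C9h2orf69 at 1.12 ± 0.52 and the histone gene H2ac25 at 1.07 ± 0.46 (SD, n = 4 each), followed by Pou3f3 at 0.92, the actin-binding Cap2 at 0.91, Aagab at 0.89, Mpp2 at 0.75, Anxa6 at 0.66 and the kinase Pak1 at 0.60. Lower by less were Arf2 (-0.66), Anp32a (-0.61), Sub1 (-0.57) and Fam110a (-0.49).

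Of the gene lists in this tissue and age, glycolysis and glucose uptake had 2 of 7 measured members higher and 0 lower, also 2 when adjusted over the list alone. These were the enzymes Aldoc (0.60 ± 0.15) and Ldha (0.46 ± 0.38) (SD, n = 4 each). In the adipocyte list 1 of 4 members, Agt, was lower and 0 higher, with 1 adjusted over the list alone, and Pparg stood at -0.11 and Lipe at -0.07 without passing. Lipid transport had 1 of 6 lower, Slc27a1, a fatty acid transport protein, at -0.61 ± 0.61 (SD, n = 4), and the respiratory chain 1 of 6 lower, Atp5pb at -0.52. Adjusted over the list alone these were 1 and 2 (1 of the 2 higher). Ccnd1 (0.44) was the 1 cell cycle gene of 5 that rose, with 2 adjusted over the list alone. None of the 9 measured members of the fatty acid oxidation list, nor of the 10 ribosomal proteins, passed over all features, though 2 ribosomal proteins were lower adjusted over the list alone. No marker of another cell type passed over all features.

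limma called 302 of 4378 features, 183 higher and 119 lower, and 48 of 848 named genes (1059 features had an unadjusted p under 0.05). Leaving out 1 array at a time gave 126 calls without array 1 and 61 without array 3, and ended the calls of Pou3f3, Mpp2, Anxa6, Arf2, Anp32a, Sub1, Atp5pb, Aldoc, Ldha, Slc27a1 and Ccnd1 (adjusted p up to 0.269, for Sub1 without array 3). A fit on these 4 arrays alone called 60, scaling the arrays to a common spread 744, and averaging arrays 1 and 3 and arrays 2 and 4 first 8, with 0 of the 20 named genes.

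Of the named genes in muscle at 6 weeks, Sncg, the gene of gamma-synuclein, was highest at 2.09 ± 0.50 (SD, n = 4). The clock repressor Nr1d1 rose by 1.06 ± 0.10 (SD, n = 4) and Aldh1a2, which makes retinoic acid, by 0.98 ± 0.07 (SD, n = 3). Sgta, a co-chaperone, was -1.19 ± 0.82 (SD, n = 3). Smaller increases were seen for Eif2b1 (0.84), Ccdc81 (0.77), Aagab (0.73) and Nkd1 (0.66). Khk, the enzyme that phosphorylates fructose, was -0.56 and Cideb was -0.53, with Hap1 at -0.38 and Fam110a at -0.34.

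Lipid transport genes were 2 of 6 higher and 0 lower, and 2 adjusted over the list alone. They were Lpl, lipoprotein lipase, at 0.70 ± 0.41 and Fabp3, the fatty acid binding protein of muscle, at 0.57 ± 0.05 (SD, n = 4 each). In the adipocyte list 1 of 2 members, again Lpl, was higher, and both were adjusted over the list alone. Lipe, the other, stood at 0.54 with an adjusted p of 0.189. Fabp3 was also the 1 of 2 slow-twitch genes called, and none of 4 fast-twitch genes passed. The respiratory chain had 1 of 9 lower (Atp5pb, -0.41) and the proteasome list 1 of 5 lower (Psmd4, -0.35). Nr1d1 was the 1 clock gene measured. None of 8 fatty acid oxidation genes passed, and no cell type marker passed over all features.

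limma called 179 of 3320 features, 105 higher and 74 lower, and 26 of 653 named genes (640 at unadjusted p under 0.05). Calls numbered 67 without array 3, 58 without array 4, 19 without both and 589 after scaling to a common spread. Averaging arrays 1 and 3 and arrays 2 and 4 first gave 43, with 5 of the 16 named genes. A fit on these 4 arrays alone called 3 features, Sncg, Nr1d1 and a probe without a symbol. That probe, at 2.76 the highest feature of the group, is not covered by the rule for named genes. Of the 16 named genes, 11 lost their call without some array (adjusted p up to 0.211, for Khk without array 2). Sncg, Nr1d1, Aldh1a2, Aagab and Sgta kept it. Without both arrays 3 and 4, Aldh1a2 (0.95) and Sgta (-0.39) rested on a single array and were not called. The fit without both had fewer than the 3 values asked for elsewhere, so a call lost there may reflect missing values.

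Liver at 6 weeks showed higher Pdk1, a kinase that switches off pyruvate dehydrogenase, at 1.36 ± 0.28 (SD, n = 4). Cd24, a surface glycoprotein, rose by 1.33 ± 0.19 and the stress kinase Mapk9 by 1.26 ± 0.29 (SD, n = 4 each). Prkar1a, a regulatory subunit of protein kinase A, was 1.19 ± 0.49 and Nr1d1 was 1.02 ± 0.20 (SD, n = 4 each), with Aagab at 1.16, Mfsd11 at 1.08 and Mpp2 at 1.07. The lowest was Cln8, a membrane protein of the endoplasmic reticulum, at -1.52 ± 0.06 (SD, n = 4). The kinase Sgk2 fell by 1.2 ± 0.19 and Thra, a thyroid hormone receptor, by 0.98 ± 0.07 (SD, n = 4 each), and Folh1 (-0.90), Ppp1r10 (-0.86), Mthfs (-0.86) and Cd63 (-0.84) were also lower.

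Fatty acid oxidation and ketogenesis had 5 of 8 measured members higher, 1 lower and 2 not called, with the same counts adjusted over the list alone. Examples were Ucp2 at 0.48 ± 0.20, Hadha, a subunit of the trifunctional protein, at 0.47 ± 0.10, and the ketone body enzyme Bdh1 at 0.44 ± 0.31 (SD, n = 4 each), with Echs1 at 0.48 ± 0.19 (SD, n = 3). Antioxidant defence had 4 of 8 higher and 0 lower, and 4 adjusted over the list alone: Gpx1 (0.75 ± 0.24), Sod2 (0.63 ± 0.32) and the regulator Nfe2l2 (0.58 ± 0.28) (SD, n = 4 each), and Hmox2 (0.57 ± 0.27, SD, n = 3). The respiratory chain had 2 of 4 higher, Atp5f1b (0.49) and Cox6a2 (0.41), and Atp5pb (-0.30) lower. Of 3 citric acid cycle genes 2 were higher, Pdk1 and Suclg1 (0.86), and 0 lower.

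Glucose genes moved both ways in this liver group. Slc37a4, the glucose 6-phosphate transporter, fell by 0.84 ± 0.26 and Pc, pyruvate carboxylase, rose by 0.63 ± 0.31 (SD, n = 4 each), the 2 of 6 gluconeogenesis genes called. In glycolysis 2 of 6 were higher and 2 lower, Aldoc (0.74) and Pgam2 (0.56) against Pfkm (-0.69) and Pfkfb1 (-0.51). The adipocyte list had 2 of 3 lower, Lipe (-0.69 ± 0.09, SD, n = 4) and Lpl (-0.68 ± 0.07, SD, n = 3), and 3 adjusted over the list alone. Lpl was also the 1 of 6 lipid transport genes called. Rps6kb1, a kinase of the insulin and IGF list, rose by 0.83 (1 of 4).

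Antigen presentation had 2 of 4 higher, RT1-M3-1 (0.82) and RT1-DMb (0.64). Macrophage and inflammation genes were 2 higher and 2 lower of 5, Spp1 (0.33) and Ccl5 (0.33) against Mmp12 (-0.29) and Il1b (-0.26), and acute phase and complement had 1 of 8 lower, C9 (-0.72). Extracellular matrix had 1 of 7 higher, Timp2 (0.89), and 3 lower, Fmod (-0.62), P4ha1 (-0.56) and Mmp14 (-0.36). Slc10a1, the bile acid importer, was 0.69 (1 of 4), Nsdhl of cholesterol synthesis 0.56 (1 of 2), and drug metabolism had Cyp3a9 (0.88) higher and Hsd17b2 (-0.77) lower of 9. Both measured clock genes were higher, Nr1d1 and Dbp (0.51), and 3 of 9 ribosomal proteins, Rps12 (0.42), Rpl37l1 (0.40) and Rpl30 (0.28), of which 1 was left adjusted over the list alone. Psmd4 (0.33) was the 1 of 5 proteasome genes called.

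Markers of other cell types also moved in liver at 6 weeks. The T cell gene Cd3d was 0.99 ± 0.18, the pancreatic genes Ctrb1 and Pnliprp1 were 0.83 ± 0.27 and 0.59 ± 0.38, and the pancreatic Cpb1 was -0.44 ± 0.04 (SD, n = 4 each). Of the skeletal muscle markers 2 of 4 were higher, Pgam2 and Myl1 (0.29), also 2 of 4 fast-twitch genes, and the smooth muscle gene Myh11 was 0.45.

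limma called 1820 of 4275 features, 913 higher and 907 lower, and 335 of 827 named genes (2134 at unadjusted p under 0.05). Without any 1 array the count stayed between 1319 and 1542, and 39 of the 62 named genes kept their call. Those that lost it were Ucp2, Echs1, Hadha, Bdh1, Sod2, Hmox2, Lipe, Pgam2, Pfkfb1, Dbp, Spp1, Ccl5, Mmp12, Il1b, Mmp14, Myl1, Myh11, Rps12, Rpl37l1, Rpl30, Atp5f1b, Cox6a2 and Atp5pb (adjusted p up to 0.294, for Mmp12 without array 3). Averaging arrays 1 and 3 and arrays 2 and 4 first gave 1009 calls with 39 of the 62 named genes, and P4ha1, Psmd4 and Cpb1 were among those lost.

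Adipose tissue at 12 weeks had higher Pparg, the regulator of fat cell differentiation, at 1.55 ± 0.33 (SD, n = 4). Crmp1, known from axon guidance, was 1.64 ± 0.42, the bicarbonate transporter Slc4a4 1.54 ± 0.69, Sncg 1.43 ± 0.76 and the chemokine Cxcl11 1.39 ± 0.44 (SD, n = 4 each). C9h2orf69 (1.45), H2ac25 (1.38) and Cyp4b1 (1.37) were also high. Dab2, an endocytic adaptor, was -1.5 ± 0.25 (SD, n = 4), low on every array. The other lowest genes rested on arrays 2 and 4: Rock1 was -2.18 ± 2.00 (SD, n = 4) with -4.15 and -3.66 on those arrays against -0.57 and -0.35 on arrays 1 and 3. Values as spread were seen for Mmp13 (-2.14 ± 1.98), Aqp9, a glycerol channel (-1.73 ± 1.71), Gzmc (-1.68 ± 1.54) and Nifk (-1.48 ± 1.33) (SD, n = 4 each), and for Krt18 (-2.12 ± 1.46) and Ggh (-1.52 ± 2.09) (SD, n = 3 each).

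Adipocyte genes had 2 of 3 measured members higher and 0 lower, and 2 adjusted over the list alone. These were Pparg and Lipe, hormone-sensitive lipase, at 1.18 ± 0.71 (SD, n = 4), and both also form the list of adipocyte markers. Lipid transport had 2 of 6 higher, Fabp3 at 1.28 ± 0.74 (SD, n = 4) and Fabp9 at 0.36. Insulin and IGF signalling had 3 of 4 lower and 0 higher, with 3 adjusted over the list alone: Igf1 (-0.69 ± 0.17), Grb2 (-0.60 ± 0.53) and Rps6kb1 (-0.25 ± 0.09) (SD, n = 4 each). Ribosomal proteins had 1 of 10 higher, Rpl41 (0.36), and 4 lower, among them Rpl7l1 (-1.15 ± 0.41), Rps24 (-0.73 ± 0.38) and Rpl31 (-0.64 ± 0.52) (SD, n = 3 each). Adjusted over the list alone they were 3 higher and 4 lower.

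Fatty acid oxidation split in this tissue, 2 of 10 higher and 2 lower. Hadha fell by 0.79 ± 0.38 (SD, n = 4) while Hadhb, the partner subunit of its complex, rose by 0.69 ± 0.47 (SD, n = 3), with Acaa2 at 0.56 and Bdh1 at -0.53. Gluconeogenesis and glycogen had 2 of 6 lower, Slc37a4 (-0.68) and Phkg2 (-0.51). Pfkl (0.24) was the 1 of 6 glycolysis genes called, and 0 were adjusted over the list alone. The respiratory chain had Atp5f1c (0.36) and Atp5pf (0.35) higher and Sdha (-0.26) lower of 6. Pdk1 (0.54) was higher, the 1 of 2 citric acid cycle genes called. Antioxidant genes were 3 higher of 6, Gpx1 (0.81), Sod3 (0.47) and Hmox2 (0.37), and 1 lower, Nfe2l2 (-0.32).

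Inflammation genes had 2 of 6 higher and 0 lower, Spp1, osteopontin, at 0.56 ± 0.23 and Tlr4 at 0.42 ± 0.13 (SD, n = 4 each), with 3 adjusted over the list alone (2 higher). Acute phase and complement had 2 of 7 lower, Mbl1 (-0.52) and C9 (-0.33). Bile acid genes had Cyp7a1 (0.35) higher and Nr1h4 (-0.38) lower of 4. Drug metabolism had 2 of 8 lower, Cyp2c12 (-0.65) and Gstm1 (-0.62). Lss of cholesterol synthesis was -0.95 ± 0.93 (1 of 4), P4hb of the chaperones -0.32 (1 of 3, 0 adjusted over the list alone) and Fmod of the matrix 0.63 (1 of 9). Aurkb (0.53) and Stmn1 (0.34) of 5 cell cycle genes rose. Nr1d1 (0.55) was higher and Dbp (-0.60) lower among 3 clock genes. Among markers of other cell types the mast cell chymase Cma1 was 1.00 ± 0.27, the T cell gene Cd3d 0.49 ± 0.13, the muscle gene Myl1 0.50 ± 0.19 and the nerve gene Cnp 0.78 ± 0.23 (SD, n = 4 each), with Gap43, also of nerve, at -0.99 ± 0.92 and pancreatic Pnliprp1 at 0.70 ± 0.30 (SD, n = 3 each).

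limma called 1537 of 4255 features, 831 higher and 706 lower, and 312 of 840 named genes (1958 at unadjusted p under 0.05). Leaving out array 2 gave 953 calls and array 4 901, and 29 of the 62 named genes lost their call without some array, Ggh (adjusted p of 0.421 without array 2), Sod3 (0.678 without array 2), Gap43, Igf1, Grb2, Rps6kb1, Tlr4, Hadhb, Bdh1, Slc37a4, Phkg2, Pfkl, Atp5f1c, Atp5pf, Sdha, Lss, Pdk1, C9, Nr1h4, Cyp7a1, P4hb, Hmox2, Nfe2l2, Rps24, Rpl31, Rpl41, Fabp9, Aurkb and Stmn1. With arrays 1 and 3 and arrays 2 and 4 averaged first, 770 features and 36 of the 62 named genes were called, with Acaa2, Mbl1, Cyp2c12 and Nr1d1 lost as well, and a fit on these 4 arrays alone did not call 24 of the 62. These were the low genes Rock1, Mmp13, Aqp9, Gzmc, Ggh and Nifk, and Lss, Hadhb, Slc37a4, Pfkl, Atp5f1c, Atp5pf, Sdha, Grb2, Rps6kb1, Cyp7a1, P4hb, Sod3, Nfe2l2, Rpl31, Fabp9, Aurkb, Stmn1 and Gap43.

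In muscle at 12 weeks Crmp1 was 2.47 ± 0.32 and Pdk1 1.99 ± 0.24 (SD, n = 4 each), and Pparg was 1.92 ± 0.46 (SD, n = 3). Map1b, a microtubule protein of neurons, rose by 1.52 ± 0.18 (SD, n = 3), and Mpp2 (1.51), Ptgs2os (1.5), Mfsd11 (1.49) and Czib (1.37) were near it. Gap43, a protein of growing axons, fell by 2.13 ± 0.54 (SD, n = 4) and Tagln3 by 1.87 ± 0.16 (SD, n = 3). Lower as well were Lgi3 (-1.24), Cd24 (-1.22), the death ligand Tnfsf10 (-1.19), Sfrp5 (-0.99), Celsr3 (-0.95) and Smg6 (-0.91).

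Both measured clock genes rose, Nr1d1 by 0.92 ± 0.14 (SD, n = 4) and Bmal1 by 0.66 ± 0.38 (SD, n = 3), and both adjusted over the list alone. Antioxidant genes had 2 of 8 higher, Hmox2 (0.93 ± 0.22) and Gclm (0.65 ± 0.27) (SD, n = 4 each), with 2 adjusted over the list alone. Antigen presentation had 2 of 4 higher, RT1-M3-1 at 0.71 and RT1-DMb at 0.59. In the adipocyte list Pparg and Agt (0.56) were higher of 4. Lipid transport had Fabp3 at 1.12 ± 0.18 (SD, n = 4) higher and Apoa1 (-0.64) and Lcat (-0.44) lower of 7. Gluconeogenesis had Fbp1 (0.66 ± 0.15) higher and G6pc1 (-0.64 ± 0.17) lower of 5 (SD, n = 4 each), and glycolysis Aldoc (0.36) higher and Ldha (-0.55) lower of 5. None of 8 fatty acid oxidation genes passed.

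The respiratory chain had Atp5pf (0.48) higher and Ndufv3 (-0.36) and Sdha (-0.28) lower of 7 in that muscle group. Ribosomal proteins had 3 of 8 higher, Rps13 (0.52), Rps15 (0.31) and Rpl37l1 (0.31), and Rpl41 (-0.40) lower. Pdpk1 of insulin signalling was 0.37 (1 of 4), Pdk1 the 1 of 3 citric acid cycle genes called, Nsdhl of cholesterol synthesis 0.49 (1 of 3) and Psmd4 0.35 (1 of 3). Ccnd1 (0.85) rose and Stmn1 (-0.30) fell among 4 cell cycle genes, and Ddit3 (0.52) rose and P4hb (-0.40) fell among 3 chaperone and stress genes. Acute phase genes had 2 of 6 lower, C9 (-0.42) and Lcn2 (-0.31). Slc10a1 (-0.71, 1 of 3 bile acid genes), Gstm1 (-0.37, 1 of 8 in drug metabolism and 0 adjusted over the list alone) and the matrix gene P4ha1 (-0.66) were lower, and Fmod (0.35) of the 3 matrix genes was higher. Fabp3 was the 1 of 2 slow-twitch and Myl1 (0.38) the 1 of 2 fast-twitch genes called, with Myl1 also a muscle marker.

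Other cell type markers moved both ways in muscle at 12 weeks. Cd3d was 0.95 ± 0.26 (SD, n = 4) while the lymphocyte gene Cd37 was -0.44 ± 0.15 (SD, n = 3). The liver gene Apoa1 was -0.64, the pancreatic Ctrb1 -0.90 ± 0.45 (SD, n = 3), the red cell gene Slc4a1 -0.32 and the nerve gene Gap43 -2.13. limma called 1453 of 3691 features, 814 higher and 639 lower, and 258 of 710 named genes (1753 at unadjusted p under 0.05). With arrays 1 and 3 and arrays 2 and 4 averaged first 853 features and 35 of the 55 named genes were called, with Myl1 among those lost, and 24 of the 55 lost their call without some array: Bmal1, Agt, Apoa1, Lcat, Slc10a1, Ddit3, P4hb, Aldoc, Ldha, Ndufv3, Sdha, Pdpk1, C9, Lcn2, Gstm1, P4ha1, Fmod, Psmd4, Rpl41, Rps15, Rpl37l1, Stmn1, Slc4a1 and Cd37 (adjusted p up to 0.378, for Aldoc without array 3).

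Liver at 12 weeks had Crmp1 at 2.39 ± 0.32, Pak1 at 1.42 ± 0.24 and G6pc1, the catalytic subunit of glucose 6-phosphatase, at 1.02 ± 0.52 (SD, n = 4 each). Tmem86a (1.11), Mpp2 (1.06), Aagab (0.93), Czib (0.90) and Pparg (0.86) were higher on every array with a value. The lowest was the kinase Syk at -1.60 ± 0.34, followed by Hagh, an enzyme that detoxifies methylglyoxal products, at -1.47 ± 0.72 and Ankrd34b at -1.45 ± 0.36 (SD, n = 4 each). Igf1, the growth factor that liver secretes, was -0.97 ± 0.82 (SD, n = 4), and Cinp (-1.27), Abi2 (-1.18), Egr4 (-1.15) and Acad11 (-0.92) were lower too.

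Gluconeogenesis and glycogen had 2 of 6 higher, G6pc1 and Fbp1 (0.58 ± 0.38, SD, n = 4), and 1 lower, Gyg1, the glycogen primer (-0.56 ± 0.40, SD, n = 3). Adjusted over the list alone 4 were higher and 1 lower. Glycolysis had Pfkm (0.49 ± 0.32) higher and Pklr, liver pyruvate kinase, (-0.40 ± 0.25) lower of 6 (SD, n = 4 each). The adipocyte list had Pparg higher and Agt (-0.88 ± 0.15, SD, n = 3) lower of 3. Igf1 was the 1 of 4 insulin and IGF genes called. Fatty acid oxidation had 1 of 7 lower, Ucp2 at -0.68 ± 0.83, and antioxidant defence Hmox2 (0.41) higher and Sod2 (-0.70 ± 0.71) lower of 7. Both chaperone and stress genes measured were called, Ddit3 (0.74) higher and P4hb (-0.29) lower.

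Pdk2 (-0.44) was the 1 of 2 citric acid cycle genes called in this liver group, and the respiratory chain had Sdha (0.36) higher and Atp5pb (-0.34) lower of 6. Psmb9 (-0.81), in both the antigen presentation (1 of 4) and proteasome (1 of 4) lists, Cyp3a9 (-0.42, 1 of 9 in drug metabolism), Lcat (-0.44, 1 of 6 in lipid transport and 0 adjusted over the list alone), Fah of amino acid breakdown (-0.31, 1 of 4) and Atp2a2 (-0.57, 1 of 2 slow-twitch genes) were lower. Ccnd1 (0.62) was the 1 of 5 cell cycle genes called. None of 7 acute phase, 7 ribosomal or 5 bile acid genes passed. Among markers, Pparg (1 of 2 adipocyte markers) was higher and pancreatic Cpb1 (-0.50, 1 of 3) lower.

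limma called 913 of 3603 features, 461 higher and 452 lower (1382 at unadjusted p under 0.05). Without array 2 the count was 349, without array 4 374, in a fit on these 4 arrays alone 398, and with arrays 1 and 3 and arrays 2 and 4 averaged first 222, with 16 of the 36 named genes and without Pparg, Psmb9 and Ccnd1. Without some array 20 of the 36 lost their call: Igf1 (adjusted p of 0.0658 without array 2), Acad11, Fbp1, Gyg1, Pfkm, Pklr, Ucp2, Sod2, Agt, Ddit3, P4hb, Hmox2, Pdk2, Sdha, Atp5pb, Atp2a2, Fah, Cyp3a9, Lcat and Cpb1.

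**Figure D2:**
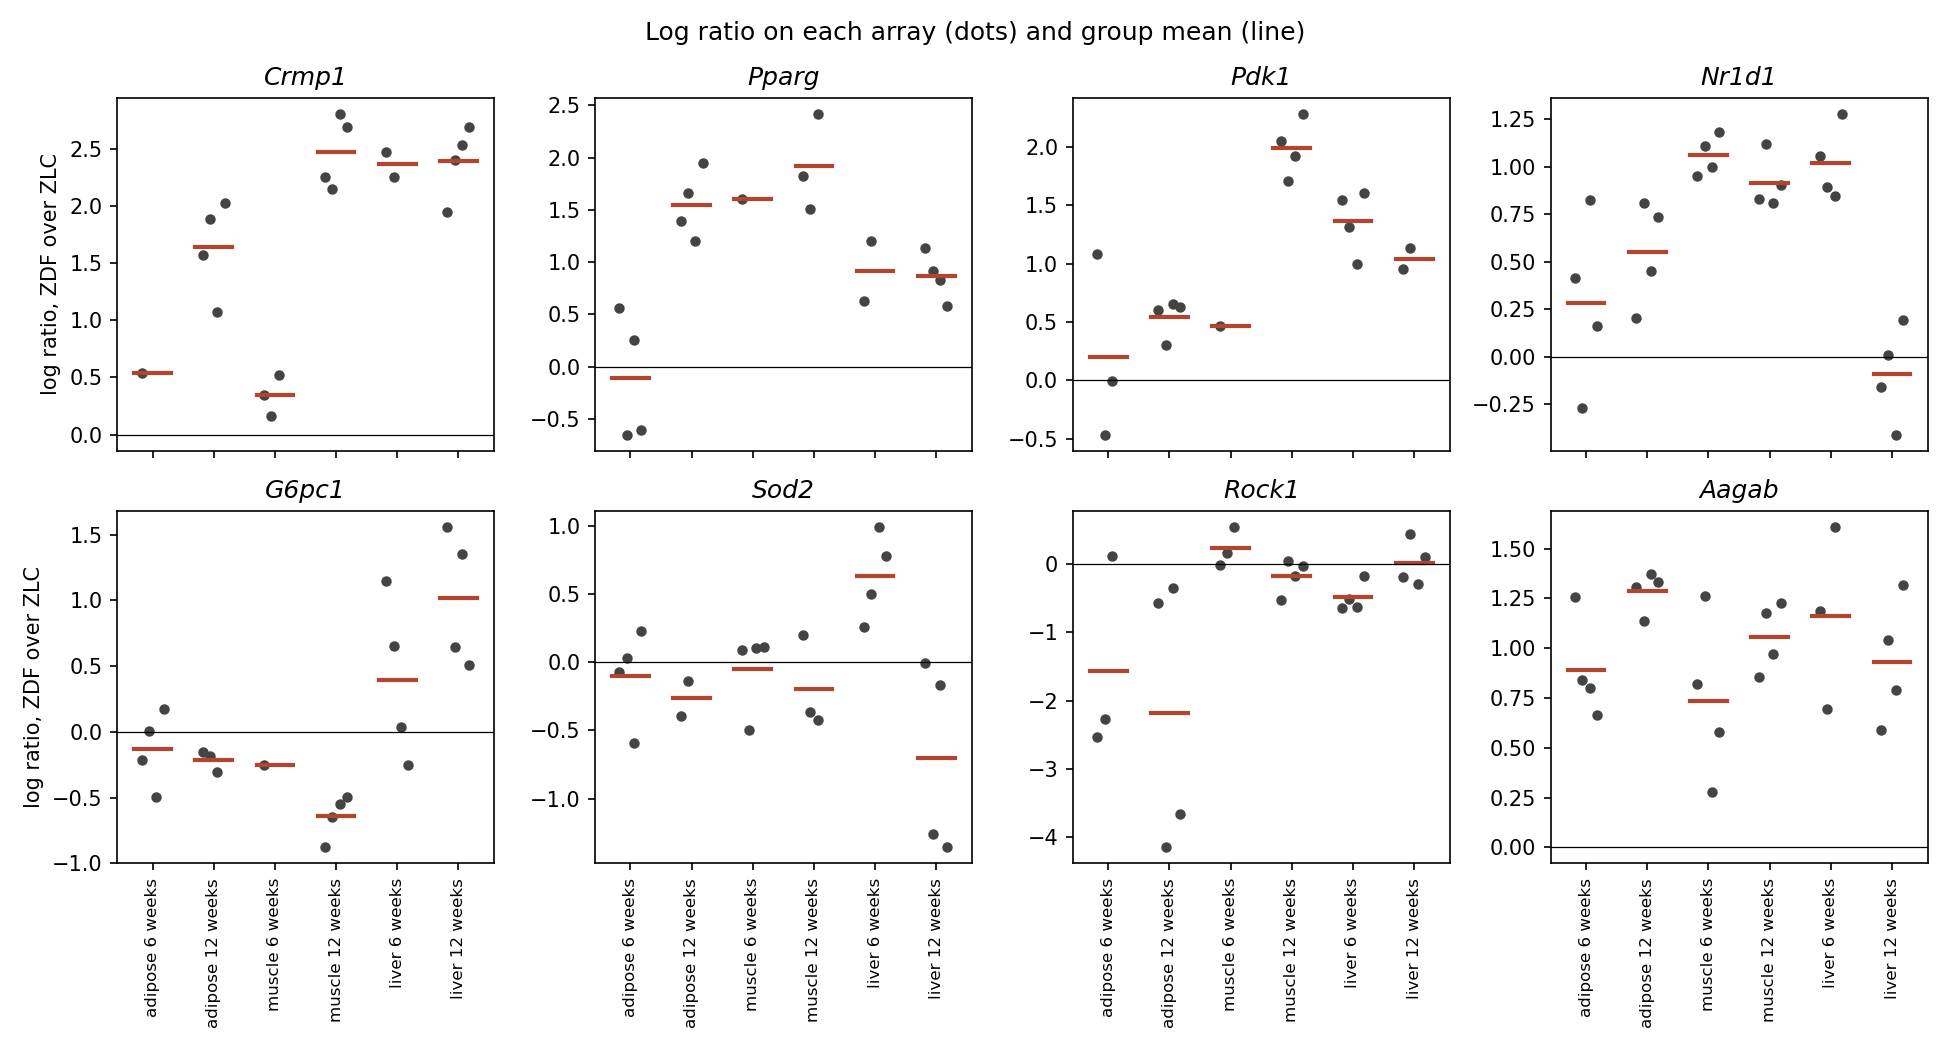
Log ratios of 8 genes on each array (dots) with the group mean (line), in adipose tissue, muscle and liver at 6 and 12 weeks; the 8 were chosen after their values were seen. Crmp1 lay between 1.07 and 2.80 on all 12 arrays of 12 weeks, and Rock1 in adipose tissue at 12 weeks split between arrays 2 and 4 and arrays 1 and 3. At 6 weeks Crmp1 was 2.47 and 2.25 on arrays 1 and 4 of liver, too few for a test, and 0.16 to 0.52 in muscle.

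The lists as wholes were not separated from the other features. Of 68 tests of 16 lists with cameraPR 0 passed and 0 had an unadjusted p under 0.05. The smallest unadjusted p was 0.0645, for lower ribosomal proteins in adipose tissue at 6 weeks (adjusted p = 0.99), and 0 passed with an estimated correlation. Of the 37 lists, 2 had no gene on the arrays, peroxisomal fatty acid oxidation and endothelial markers, and the others held few: of fatty acid synthesis Scd was measured in adipose tissue and 1 gene in liver at 6 weeks, and neither passed. The 1 fibroblast marker did not pass in any group over all features.

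The log ratio at 12 weeks was compared with that at 6 weeks within each tissue. In adipose tissue Pparg (1.66 ± 0.26), Fabp3 (1.31 ± 0.22) and the stress gene Nupr1 (1.30 ± 0.24) were higher relative to lean at 12 than at 6 weeks (difference ± SE, up to 8 arrays). Agt (1.64) and Lipe (1.26) were higher and Gap43 (-1.16), Hao2 (-1.14), Il6st (-1.11), P2rx1 (-1.08) and Tagln3 (-1.03) lower. limma called 163 of 3961 features, 116 higher and 47 lower, with 33 named genes. Without each array in turn Pparg, Fabp3 and Nupr1 kept the call and the other 7 genes lost it at least once (adjusted p up to 0.199), with counts of 30 and 32 without arrays 2 and 4 of 6 weeks, 302, 33, 247 and 15 without arrays 1 to 4 of 12 weeks, and 285 with array weights. A fit on these 8 arrays alone called 0 features, as did averaging arrays 1 and 3 and arrays 2 and 4 first, and a split of the same arrays that crosses age called 378.

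Of the named genes in muscle Crmp1 rose most between the ages (2.13 ± 0.23, difference ± SE, up to 8 arrays), with Scly (1.21), Faah (1.17 ± 0.16), Mapk9 (1.13 ± 0.19) and Sort1 (1.13 ± 0.23). Sncg (-1.95 ± 0.38), Gap43 (-1.92 ± 0.26), the anti-inflammatory Anxa1 (-1.68 ± 0.37), Lgi3 (-1.47) and Cd24 (-1.37) were lower at 12 weeks. Hap1 and Psmd4 went from lower than lean at 6 weeks to higher at 12 weeks, and their differences stayed called without any 1 array, while the calls at each age were lost without some array (adjusted p up to 0.357). Among cell markers Cd3d (0.76) and Myl1 (0.59) were higher and Ctrb1 (-0.99) lower, beside Gap43. Other markers were not called, among them Cd37 (-0.35), Pnliprp1 (0.07), Slc4a1 (-0.32), Pgam2 (0.18), Myh11 (0.17) and Cma1 (-0.21). limma called 557 of 2897 features, 328 higher and 229 lower, and 94 named genes. Counts were 367 without array 3 of 6 weeks, 368 without array 4 of 12 weeks, 217 without arrays 3 and 4 of 6 weeks and 164 with arrays 1 and 3 and arrays 2 and 4 averaged first, where Sncg, Anxa1 and Cd24 were not called. The share of calls that were higher was 58.9%, and 48.6% with the values as deposited (41.1% and 51.4% if the ratio ran the other way); Scly lost its call without array 3 or 4 of 6 weeks or array 1 or 2 of 12 weeks (adjusted p up to 0.132).

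In liver the largest number of features differed between ages, 1324 of 3394. Cln8 (1.47 ± 0.17), Slc37a4 (1.28 ± 0.26), Pfkm (1.18 ± 0.17), Gtf2a1 (1.14) and Lrsam1 (1.12) were higher relative to lean at 12 weeks, and Prkar1a (-2.01 ± 0.28), Cd24 (-1.90 ± 0.30), Syk (-1.87 ± 0.23), Egr4 (-1.66 ± 0.27) and Upb1 (-1.56) lower (difference ± SE, up to 8 arrays). In 192 features the 6-week and the 12-week call had opposite signs and the difference itself was called, 113 high then low and 79 low then high. Sod2 went from 0.63 to -0.70, Ucp2 from 0.48 to -0.68, Cyp3a9 from 0.88 to -0.42 and Pfkm from -0.69 to 0.49. Their differences stayed called without any 1 array, but the 12-week call of each of these 4 was lost without array 2 and without array 4 of 12 weeks (adjusted p up to 0.216, for Cyp3a9), and the 6-week call without each array for Ucp2 and without array 3 for Sod2. Of the 36 named genes of this kind, 36 kept the call of the difference without any 1 array, 19 the call at 6 weeks and 3 that at 12 weeks. If calls at both ages were independent, 189.8 would have opposite signs, so the 192 are no excess. Features higher at both ages numbered 191 against 99.2 from independent calls, and features lower at both ages 61 against 90.6. Both ages share a residual variance per feature, so their calls are not strictly independent and these comparisons only describe the overlap. Among cell markers Cd3d (-0.82), Pnliprp1 (-0.93), Ctrb1 (-0.67), Pgam2 (-0.90) and Myl1 (-0.48) were lower relative to lean at 12 weeks. Other markers were not called, among them Cpb1 (-0.06), Cd37 (-0.14), Slc4a1 (-0.36), Gap43 (0.37) and Lipe (0.66). limma called 635 features higher and 689 lower, with 239 named genes, and each of the 10 highest and lowest named genes kept the call without any 1 array. Averaging arrays 1 and 3 and arrays 2 and 4 first gave 618 calls.

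Across features the group means of liver at 6 and 12 weeks were nearly unrelated (Pearson 0.04, rank correlation -0.05), while those of adipose tissue were related (Pearson 0.64, rank correlation 0.57). Muscle had a Pearson correlation of 0.25 and a rank correlation of 0.28. Both liver groups were closer to muscle at 12 weeks than to each other. Against it, liver at 6 weeks had a Pearson correlation of 0.47 and a rank correlation of 0.40, and liver at 12 weeks 0.45 and 0.36. These are correlations across features within group means, and features are not independent replicates.

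The log ratios of ZDF over lean were compared between tissues over both ages, so the values are differences in that ratio and not in the level of expression, which no array compared between tissues. The log ratio of G6pc1 was higher in liver than in adipose tissue (0.88 ± 0.19). Among called genes, the 5 highest differences were Mmp13 (1.69), Rock1 (1.64), Rab11a (1.42), Nxph3 (0.97) and Dapp1 (0.93). Hagh (-1.49 ± 0.22), Cyp4b1 (-1.29 ± 0.22), H2ac25 (-1.21), C9h2orf69 (-1.2) and Acad11 (-1.17) had lower log ratios in liver, as had Lipe (-0.92 ± 0.23) and Fabp3 (-0.79 ± 0.16) (difference ± SE, up to 16 arrays). Among cell markers beside Lipe, Myl1 (-0.35) and Cpb1 (-0.39) had lower and the fibroblast gene S100a4 (0.44) higher log ratios in liver. Other markers were not called, among them Ctrb1 (0.30), Pnliprp1 (-0.26), Cd3d (0.26), Cd37 (0.18) and Pgam2 (-0.05). G6pc1, Lipe and Fabp3 were picked here after their values were seen. limma called 653 of 2999 features, 286 higher and 367 lower, with 104 named genes. Averaging arrays 1 and 3 and arrays 2 and 4 first gave 76 and ended the calls of the 5 highest, Mmp13, Rock1, Rab11a, Nxph3 and Dapp1, and exchanging the tissues at 12 weeks gave 863, more than the tissue split itself; Nxph3 lost its call without array 3 of adipose tissue at 6 weeks (adjusted p 0.0723).

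Between liver and muscle, the log ratio of ZDF over lean was higher in liver for Gap43 (1.06 ± 0.19), Cd24 (0.92 ± 0.22), Ctrb1 (0.90 ± 0.14), Rabggta (0.80) and Slc10a1 (0.77). It was lower in liver for Fabp3 (-1.0 ± 0.16) and Nr1d1 (-0.52 ± 0.13), with Ccdc81 (-0.79), Gmpr2 (-0.69) and Defa5 (-0.63) (difference ± SE, up to 16 arrays). Nr1d1 and Gap43 differed mainly at 12 weeks. At 6 weeks Nr1d1 was 0.84 to 1.28 on the liver arrays and 0.95 to 1.18 on the muscle arrays. At 12 weeks it was -0.09 in liver and 0.92 in muscle. Gap43 in muscle was -0.21 at 6 weeks, with a difference between ages of -1.92. limma called 157 of 2440 features, 87 higher and 70 lower, with 29 named genes. Array weights gave 360 calls, averaging arrays 1 and 3 and arrays 2 and 4 first 14, and exchanging the tissues at 12 weeks 817; with the averaged arrays 0 of the 10 highest and lowest genes were called. Without muscle arrays 3 and 4 of 6 weeks 104 were called, and Nr1d1 was not (adjusted p 0.0568). Ccdc81 was not called either (-0.65), with a single value left in muscle at 6 weeks.

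Between adipose tissue and muscle, the log ratio of ZDF over lean was higher in adipose tissue for Cd24 (1.46 ± 0.24), Acad11 (1.28 ± 0.19), Ppp2r3a (1.15 ± 0.18), Cxcl11 (1.11 ± 0.29) and Selenop (1.11 ± 0.19), and lower for Rock1 (-1.90 ± 0.47), Rab3ip (-0.98 ± 0.14), Dapp1 (-0.95 ± 0.21), Pcm1 (-0.82) and Ptprf (-0.70) (difference ± SE, up to 16 arrays). The log ratios of 5 markers of other cell types were higher in adipose tissue as well, nerve Gap43 by 0.76, mast cell Cma1 by 0.74, pancreatic Ctrb1 by 0.60 and Pnliprp1 by 0.45, and muscle Myl1 by 0.32. Other markers were not called, among them Cd3d (-0.25), Cd37 (0.21), Slc4a1 (0.06), Pgam2 (0.12) and Myh11 (-0.14). limma called 584 of 2546 features, 359 higher and 225 lower, with 108 named genes. Averaging arrays 1 and 3 and arrays 2 and 4 first gave 168 calls and ended those of Rock1, Dapp1, Pcm1 and Ptprf, and Pcm1 and Ptprf also lost their call without some array (adjusted p up to 0.0917).

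Some genes were called the same way in nearly every group. Aagab and C19h19orf53 were higher in all 6, Il1r2 in the 5 groups where it was tested, and Mpp2, Myl11 and Pak1 in 5 of 6 (C19h19orf53, Il1r2 and Myl11 chosen after their values were seen). In all, 38 of 3377 features were called the same way in at least 5 groups, 35 higher and 3 lower. Because Cy5 always carried ZDF RNA, a dye effect of such a probe stands in the same place as a ZDF difference. Aagab, C19h19orf53 and Il1r2 did not differ among groups by the F-test of limma (adjusted p 0.175, 0.211 and 0.54), which Mpp2, Myl11 and Pak1 did (0.0126, 0.00719 and 5.18e-05). Crmp1 was positive on every array with a value but was tested in too few groups to be counted here.

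**Figure D3:**
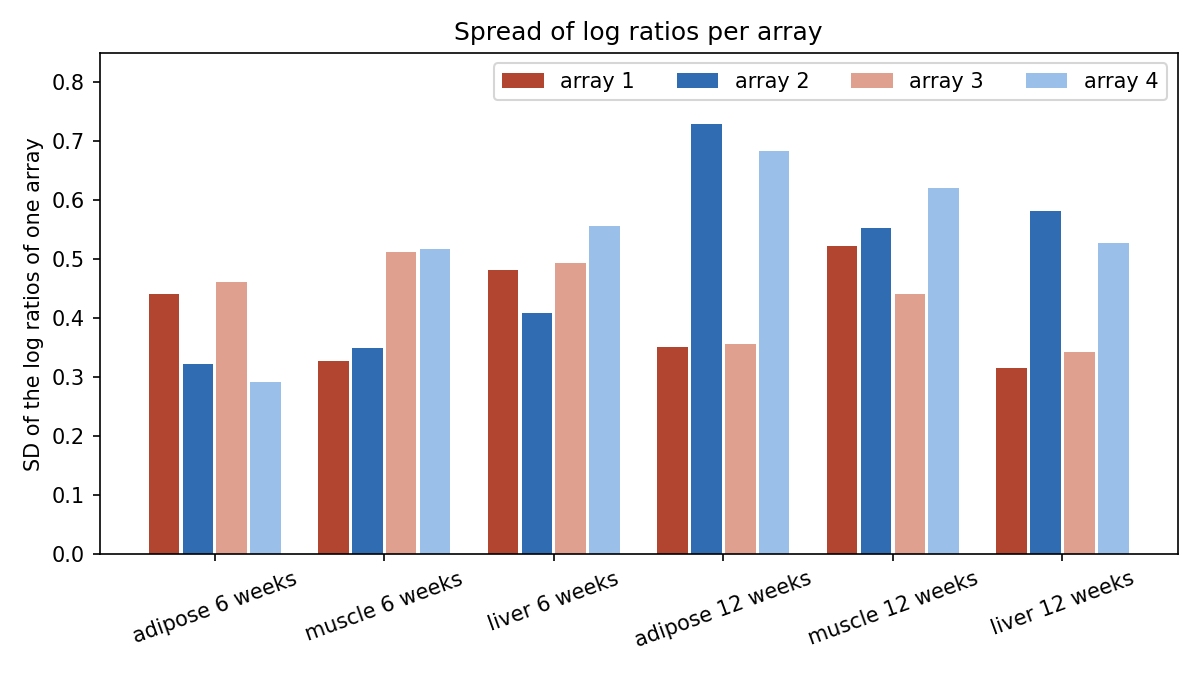
Bars give the standard deviation of the log ratios of each array, for arrays 1 to 4 of each group. In adipose tissue at 12 weeks arrays 2 and 4 had 0.729 and 0.683 against 0.351 and 0.357 on arrays 1 and 3, and in liver at 12 weeks arrays 2 and 4 had 0.582 and 0.527 against 0.316 and 0.343.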

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

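Of the tests below, those of a difference common to all muscle arrays, of the odd and even arrays, of a dye effect of 1 size and of tissues exchanged at 12 weeks were chosen only after the result was seen.

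A single array lay far from the other 3 in 10 of the 191 named results with 4 values, about the 1 in 20 that chance gives. The figure for each is the gap to the nearest array over the whole range. In muscle at 6 weeks Atp5pb had 0.89 (array 4 high). In liver at 6 weeks Mthfs had 0.939 (array 4 high), Lipe 0.855 (array 2 high), Rpl30 0.850 (array 4 low) and Ctrb1 0.944 (array 3 high, 1.24 against 0.71 on the nearest). In adipose tissue at 12 weeks Pdk1 had 0.851 (array 2 low). In muscle at 12 weeks Sfrp5 had 0.835 (array 3 high, -0.12 against -1.20), Rps13 0.937 (array 1 low), Rpl37l1 0.934 (array 1 low) and Slc4a1 0.864 (array 2 low, -0.73 against -0.22). The number of values per array in liver at 6 weeks had 0.855, with 3888 on 1 array and 4290 on the next.

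Log ratios differed between ages by the test of the difference in 163 features in adipose tissue, 557 in muscle and 1324 in liver. They differed between tissues in 653 (liver against adipose tissue), 157 (liver against muscle) and 584 (adipose tissue against muscle). Over all features, opposite calls at the 2 ages were no excess over independent calls, with 192 against 189.8 in liver and 12 against 30.8 in muscle. Named genes called in opposite directions at the 2 ages, with the difference itself called, numbered 3 in muscle and 36 in liver. Those in muscle were Hap1 (difference 0.70), Psmd4 (0.70) and Mapk14 (-0.74). Those in liver that the rule for named genes had picked were Prkar1a (-2.01), Egr4 (-1.66), Upb1 (-1.56), Sod2 (-1.33), Cyp3a9 (-1.30), Ucp2 (-1.16), Pfkm (1.18), Gtf2a1 (1.14) and Lrsam1 (1.12).

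Among the 35 splits of 8 arrays, chance was excluded for the age difference in muscle (557 against 43 at most in the others, 1 split as large) and in liver (1324 against 109, 1 split as large). It was not excluded in adipose tissue, where 2 of 35 splits were as large and the highest other gave 378 against 163. That split set arrays 1 and 3 of 6 weeks with arrays 2 and 4 of 12 weeks, the arrays with the wider spread at each age, and points to a structure of the arrays beside age. Of 100 splits drawn for each pair of tissues, chance was excluded for adipose tissue against muscle (584 against 280 at most, 1 as large). For liver against adipose tissue 1 of the 100 was as large (653 against 304) and for liver against muscle 2 were (157 against 475). Both shares lie under 0.05, the bound also used for adipose tissue against muscle. By that bound the draws argue against chance, though for liver against muscle a drawn split gave 475. Neither count stood above all regroupings, as the exchanges below show. An exchange at 12 weeks measures how a tissue difference changes with age, so its count is no measure of chance. The arrays therefore hold a structure beside tissue. The split with 475 set all 4 liver arrays of 6 weeks with 3 muscle arrays and 1 liver array of 12 weeks. Exchanging the 2 tissues wholly at 12 weeks called 817 against 157 for liver and muscle and 863 against 653 for liver and adipose tissue. For adipose tissue and muscle it called 227 against 584. The differences that involve liver therefore depend on age, and the 227 leave open a smaller dependence on age for adipose tissue against muscle. All of these exclusions take the arrays as independent samples; with 2 RNA samples per group, which stays open, the splits would be too few for a share under 0.05.

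For a single group, the 8 sign patterns of 4 arrays are too few for a share under 0.05. The real count was 302 against 5 in the highest other pattern for adipose tissue, 179 against 40 for muscle and 1820 against 82 for liver at 6 weeks. At 12 weeks it was 1537 against 174, 1453 against 152 and 913 against 91, with 1 pattern, the real one, as large in each of the 6 groups.

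Arrays 1 and 3 differed from arrays 2 and 4 in adipose tissue at both ages and in liver at 12 weeks: in adipose tissue at 6 weeks arrays 1 and 3 had r 0.656, arrays 2 and 4 r 0.562 and pairs across these 2 sets 0.219 on average. A batch shared by array number was argued against by the differences between the sets, which correlated at most 0.0319 between groups and -0.612 between the adipose ages, but that negative value leaves open a batch that joins arrays 1 and 3 of 6 weeks with arrays 2 and 4 of 12 weeks. The same profile measured with different compression was argued against by correlations within the sets that exceeded those across by 0.191 or more. The correlation of blank cells was higher within the sets than across by 0.0696 at most, which leaves open whether 2 RNA samples per group were each put on 2 arrays: these cannot be told apart from 4 samples, since the value lies between no excess and the 0.1 asked for, and the rule for blank cells is not given in the sources used here. If they were, the number of independent samples may be 2 per group, and averaging each set first gave 8 calls in adipose tissue at 6 weeks in place of 302; a difference between animals of a group is untested.

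In muscle at 6 weeks 14 probes, 0 of them with a gene symbol, were below -2 on both array 3 and array 4, with medians of -3.53 and -3.74. Arrays 3 and 4 had r 0.705, and 0.545 without these probes. A difference between ZDF and lean muscle common to all 4 arrays was argued against by the median of -0.11 on arrays 1 and 2 (20 values, quartiles -0.31 and 0.13). RNA of another tissue in the lean RNA of these arrays may be the source. The probes were blank 1.42 times as often as others on muscle arrays of 12 weeks (19.6% against 13.8%), a ratio too near 1 for 14 probes to decide. Outside that prediction, blank shares at 6 weeks were 14.3% against 5.8% in muscle, 37.5% against 10.9% in liver and 10.7% against 10.5% in adipose tissue. At 12 weeks they were 23.2% against 15.4% in liver and 17.9% against 10.8% in adipose tissue. A difference between the animals on arrays 3 and 4 stays open as untested.

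In 38 features the same direction was called in at least 5 groups, 63.6 times the 0.598 that independent calls give. The excess argues against an overlap of independent calls. All groups share a residual variance per feature, however, so their calls are not independent even without a common cause. How much of the excess that sharing gives was not tested. Of the 38, 27 or 71.1% differed among groups, but so did 64.0% of all 3377, so this test could not decide on a dye effect of 1 size on every array: such an effect with ordinary group differences on top would give the same share. A dye effect may therefore be the source for all 38, Aagab, C19h19orf53 and Il1r2 among them, and stays open, as does a difference between the lines common to all tissues.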

How the results depend on the processing

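Main settings and the alternatives below were chosen before the data were examined; the exceptions, tests chosen only after the result was seen, are the average of arrays 1 and 3 and of arrays 2 and 4, and the fit without muscle arrays 3 and 4 of 6 weeks. Unless a construction is named, the cause was not tested. With values as deposited, every probe on its own, at least 2 of 4 values, or the replicate number as a block, all 12 counts stayed within 1.5 times the reported one. Named calls lost were 13 with values as deposited, 3 with at least 2 of 4 values and 1 with the block. The random block gave 302, 180, 1821, 1538, 1453 and 914 calls for the 6 groups (adipose tissue, muscle and liver at 6, then 12 weeks), with a consensus correlation of -0.0132 from a fit that treats missing values approximately. Equal numbers did not pair arrays over all tissues: r of 24 such pairs ran from -0.18 to 0.20, and the own number was best in 8. The exception was muscle with liver at 12 weeks, where all 4 pairs were positive (0.0857, 0.132, 0.205 and 0.172) and the own number was best in 3, with 1 pair under the 0.1 asked of every pair. With fixed blocks, which fit the tissue differences only, liver against adipose tissue had 566, liver against muscle 120 and adipose tissue against muscle 545. The list tests gave 0 calls in every setting run (cameraPR, 0 at unadjusted p under 0.05). Scaling to a common spread gave 744 in adipose tissue and 589 in muscle at 6 weeks, but 41 named calls were lost with it. Values on all 4 arrays, which test fewer features, gave 119 in muscle at 6 weeks, 294 and 799 for the age differences of muscle and liver, 248 for liver against adipose tissue, 40 for liver against muscle and 189 for adipose tissue against muscle. A fit on the compared arrays only gave 60 in adipose tissue and 3 in muscle at 6 weeks, 398 in liver at 12 weeks and 0 for the adipose age difference. Array weights gave 285 for that difference and 360 for liver against muscle, and 29 named calls were lost with them. The averaged arrays, with fewer values, gave 8, 43, 1009, 770, 853 and 222 for the groups in the order above, 0, 164 and 618 for the age differences of adipose tissue, muscle and liver, and 76, 14 and 168 for liver against adipose tissue, liver against muscle and adipose tissue against muscle. With them 152 of the 311 named calls were lost and 159 kept, and in the fit on the compared arrays only 85 were lost. Those 85 were all but Sncg and Nr1d1 in muscle at 6 weeks, all 10 of the adipose age difference, Scly in that of muscle, and Ptprf in adipose tissue against muscle. The others were, in adipose tissue at 6 weeks, Pou3f3, Mpp2, Anxa6, Arf2, Anp32a, Sub1, Atp5pb, Fam110a, Ldha, Slc27a1 and Ccnd1. At 12 weeks they were 24 genes in adipose tissue, Aldoc, Sdha, Pdpk1, Lcn2, P4hb, Fmod, Psmd4, Rpl37l1, Stmn1 and Slc4a1 in muscle, and Ucp2, Gyg1, Pfkm, Pklr, Sdha, Atp5pb, Cyp3a9, P4hb, Atp2a2, Sod2, Hmox2, Lcat, Fah and Cpb1 in liver. With the averaged arrays 0 were kept in adipose tissue at 6 weeks, its age difference and liver against muscle, and all 10 in the liver age difference. Those lost in muscle at 6 weeks were Eif2b1, Ccdc81, Lpl, Nkd1, Khk, Cideb, Atp5pb, Hap1, Psmd4, Fam110a and Fabp3. In liver at 6 weeks they were Ucp2, Echs1, Hadha, Bdh1, Pgam2, Atp5f1b, Cox6a2, Atp5pb, Lipe, Spp1, Ccl5, Mmp12, Il1b, P4ha1, Mmp14, Myl1, Psmd4, Sod2, Rps12, Rpl37l1, Rpl30, Cpb1 and Myh11. In adipose tissue at 12 weeks they were Lss, Acaa2, Bdh1, Slc37a4, Pfkl, Atp5pf, Sdha, Pdk1, Igf1, Grb2, Rps6kb1, Tlr4, Mbl1, C9, Nr1h4, Cyp7a1, Cyp2c12, P4hb, Sod3, Hmox2, Nfe2l2, Rpl41, Fabp9, Nr1d1, Aurkb and Stmn1. In muscle at 12 weeks they were Ldha, Aldoc, Ndufv3, Sdha, Pdpk1, Agt, C9, Lcn2, Gstm1, Ddit3, P4hb, Fmod, Myl1, Rps15, Rpl37l1, Lcat, Bmal1, Stmn1, Slc4a1 and Cd37, and in liver at 12 weeks Pparg, Igf1, Ucp2, Fbp1, Pfkm, Pklr, Sdha, Atp5pb, Pdk2, Agt, Psmb9, Cyp3a9, Ddit3, P4hb, Sod2, Hmox2, Lcat, Fah, Ccnd1 and Cpb1. The muscle age difference lost 3, liver against adipose tissue 5 and adipose tissue against muscle 4. Without muscle arrays 3 and 4 of 6 weeks, muscle at 6 weeks had 19, its age difference 217 and liver against muscle 104.

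Without 1 array at a time, calls ran from 61 to 294 in adipose tissue, 58 to 162 in muscle and 1319 to 1542 in liver at 6 weeks, and from 901 to 1464, 1019 to 1415 and 349 to 1026 at 12 weeks. For the age differences they ran from 15 to 302 in adipose tissue, 367 to 651 in muscle and 1000 to 1383 in liver, and for the tissue differences from 460 to 716, 106 to 177 and 442 to 628 in the order above. Arrays that moved a count by over 1.5 times were adipose 6 weeks 1 (126) and 3 (61), muscle 6 weeks 3 (67) and 4 (58), adipose 12 weeks 2 (953) and 4 (901), and liver 12 weeks 2 (349) and 4 (374). For the adipose age difference they were 6 weeks 2 (30) and 4 (32) and 12 weeks 1 (302), 2 (33), 3 (247) and 4 (15), and for that of muscle 6 weeks 3 (367) and 12 weeks 4 (368).

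Subtracting the mean of the other 2 tissues removes a shared dye effect and asks another question. It gave 905 calls in liver at 6 weeks and 757, 778 and 598 in adipose tissue, muscle and liver at 12 weeks. This alternative covers group results only, and not all of them. Of those covered, 107 stayed the same and 67 lost their call without reversing. Of 318 named results, 17 reversed, all under this alternative. Those called in reverse were Crmp1 in adipose tissue (-0.79, adjusted p 0.00372) and Pparg in liver (-0.87, adjusted p 0.0151) at 12 weeks. The others were at 6 weeks Aagab in adipose tissue (-0.056) and muscle (-0.29), Atp5pb in muscle (0.0042) and liver (0.16) and Fam110a in muscle (0.031). At 12 weeks they were Atp5pf (-0.022), Igf1 (0.026), P4hb (0.027), Hmox2 (-0.30), Cd3d (-0.073) and Gap43 (0.037) in adipose tissue and Mpp2 (-0.30), Aagab (-0.24), P4hb (0.064) and Hmox2 (-0.23) in liver. Signal over background is not in the files, so its limits could not be given.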

Other observations

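Some named genes with opposite calls at the 2 ages in liver lie outside the lists and were chosen after their values were seen. Tst, a mitochondrial sulfur transferase, was 0.79 at 6 and -0.53 at 12 weeks, Sgk1, a kinase induced by glucocorticoids, 0.40 and -0.51, and Tigar, which lowers fructose 2,6-bisphosphate, 0.43 and -0.46. In the other direction Nr3c2, the mineralocorticoid receptor, was -0.50 and 0.33, Hes1, a Notch target, -0.46 and 0.41, and Acvrl1 -0.44 and 0.50. In muscle Mapk14, the p38 kinase, went from 0.43 to -0.31. The 36 named genes of this kind in liver and 3 in muscle were picked by a called difference. Passing the limma test of the difference is therefore no further support for them. Its adjusted p ran up to 0.00465 for Ywhab in liver and 0.00437 for Hap1 in muscle. Without each array in turn each difference stayed called, but Sgk1 was the 1 gene whose calls at both ages stayed as well.

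The hypothesis that genes near Lepr differ because the lines differ around the fa mutation was set before the result was seen. The median size of the log ratio over 10 measured neighbours was 0.17, against 0.12 for 581 runs of 10 neighbouring genes. Of the runs 20.3% were as large or larger, so these data do not set the 10 neighbours apart. Only 770 measured genes could be placed, so the 10 may reach far from Lepr. The median therefore cannot decide on a narrower segment around the mutation. Among the 10 neighbours Czib had a size of 0.81.

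Rock1 in adipose tissue was low on different arrays at the 2 ages. At 6 weeks it was -2.54 and -2.27 on arrays 1 and 3 and 0.13 on array 4, and at 12 weeks -4.15 and -3.66 on arrays 2 and 4.

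Probes of the same gene did not always move together. In liver at 6 weeks the pair for Nfat5 had -0.16 and 0.55, that for Ipmk -0.66 and -0.18, and that for Tcf12 -0.23 and 0.49.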
